A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

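Bacteroids and free-living cells of *Bradyrhizobium diazoefficiens* USDA 110 were compared on 6 arrays of 2 colours. Per the labels' protocols, total RNA was extracted with hot phenol, copied into cDNA with random hexamers and coupled to Cy3 or Cy5. Per the series design text, 3 independent materials were prepared of each cell type, and each was hybridised in both dye orientations. The values analysed are the signed log ratio of the channels, as deposited by the authors, with 1 value per row and array. Image analysis, background correction, normalization and filtering are not given in the sources used here. Negative values exclude a linear ratio. Array medians between -0.0099 and -0.0014 mean that the arrays were centred or nearly so. SDs per array lay between 0.114 and 0.147, and values between -0.867 and 1.004. The base of the logarithm is not stated and could not be settled from the values; the plan had assumed base 2, so sizes are given for base 10 and base 2. The direction is not stated either. All arrays correlated positively, so no sign was changed, and bacteroid over free-living was taken as likely from the series title and sample descriptions; values of single genes were not used for this.

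Missing values numbered 14 to 129 per array, 8290 of 8480 rows had a value on all 6 arrays, and 10 had none. Rows were named through a platform annotation of 2007, which listed 8462 rows with 1 symbol each, 0 with several and left 18 unnamed. It gives no products, and the other gene table at hand shares no identifiers with it, so no coordinates are printed. Of 8269 genes, 1446 had a symbol other than their locus tag. Rows of the same gene were averaged (402 rows in 191 genes). A lowered or raised copy can share signal with a near-identical copy, which these values cannot separate. No control, ribosomal RNA or plant rows were found (0).

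The swapped arrays of a material were averaged, so that a dye effect cancels, and the 3 materials were the replicates. An intercept was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend, 2 residual degrees of freedom and 3.72 prior degrees of freedom), for the 8221 genes with a value in all 3 materials; 48 genes were not tested. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05. An exact sign-flip test on 3 materials cannot go below 0.25, so no such test is given. The dye effect was fitted in the same way on the difference between the swapped arrays over 2. Gene lists were tested with camera (preset correlation 0.01) where at least 5 members were measured, with Benjamini-Hochberg over 22 lists. Figures were drawn with matplotlib 3.10.9.

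Gene lists, the rule for named genes, the tests and most alternatives were chosen before the data were examined. Named genes are, among genes with a symbol that passed with the same sign on all 6 arrays, the 10 highest and 10 lowest, a fixed set of anchor genes whatever their result, and the called member of largest size in each tested list. Other list members and genes without a symbol were named after their values were seen. Lists were formed from symbols alone; 4 lists fixed on product words (ABC transporters, transposases, transcriptional regulators and aminoacyl-tRNA synthetases) were not analysed here. Of 23 lists formed, the trehalose list had 2 members and was not tested.

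On simulated values for 8221 genes and 3 materials, the fit recovered 51% of 100 genes changed by 0.15 and 93% of 100 changed by 0.3, with 4 false calls among 148. Among 22 lists on noise, 0 were called. The simulated genes were drawn independently of each other, with spreads from the prior that limma fitted, which favours few false calls. A far smaller share of them was changed than the 27.9% that passed in the real data, so recovery there may differ. In the real lists the estimated correlation ran from -0.04 (cell division and wall) to 0.99 (ATP synthase). The simulated counts thus say nothing on false calls among genes that move together. Alternatives covered centring, scaling between arrays, the unit of replication, each dye orientation alone, each material left out, missing values, rows of a gene, the variance model, a minimum size, the correlation within lists, another set test and list members. The base 10 sizes, an uptake hydrogenase list without hupA and hup, and an estimated correlation for 2 list calls made under another setting were added after seeing the data.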

Results

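Transcripts of *Bradyrhizobium diazoefficiens* USDA 110, the bacterium that fixes nitrogen in soybean root nodules, were compared between bacteroids and free-living cells. Bacteroids are the nitrogen-fixing form that the bacteria take inside nodules. The series design text gave 3 independent biological materials of each kind, which the labels number as replications. Each pair was hybridised to 2-colour arrays in both dye orientations, which made 6 arrays. The deposited values were log ratios for 8480 rows, of which 8351 to 8466 had a value on each array. After rows of the same gene were averaged, 8221 genes had a value in all 3 materials. Growth medium, host plant and nodule age are not given in the sources used here. The number of arrays limits the precision of every value.

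All values are in deposited log ratio units, and 2 properties of them are not stated. The base of the logarithm is unknown, so a log ratio of 0.30 is 2-fold if the base is 10 and smaller if it is 2. The direction is also unknown; bacteroid over free-living is likely, from the series title and the sample descriptions, and is used throughout. If the ratios ran the other way, every "higher" and "lower" would exchange. Array medians lay between -0.0099 and -0.0014, so the ratios are relative to a typical gene. Values are the mean ± SD over materials (n = 3), with limma's adjusted p.

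The first comparison asked which genes differed between bacteroids and free-living cells. Of 8221 genes, 2293 (27.9%) passed the threshold, 1014 higher and 1279 lower in bacteroids. The counts of called members in gene lists given below are to be read beside this share. Differences were mostly small: the median size among these genes was 0.15, equal to 1.40-fold if the base is 10 and 1.11-fold if it is 2. A size of 2-fold was reached by 260 of them (178 higher, 82 lower) if the base is 10 and by 0 if it is 2. The count depended on which material was left out: it was 924 without material 1, 2497 without material 2 and 1150 without material 3. A plain one-sample test per gene, which does not share information on the spread between genes, called 1 gene.

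Among genes with a symbol, the highest value belonged to rhlE (bll1447), named for an RNA helicase, at 0.53 ± 0.066 (adjusted p = 5.3e-04), which is 3.39-fold if the base is 10 and 1.44-fold if it is 2. It was followed by phoD (bll7946), an alkaline phosphatase name, at 0.52 ± 0.11 (adjusted p = 0.0014). Next came hypA (bll6932), a nickel-insertion factor of hydrogenase, at 0.49 ± 0.066. The malonate decarboxylase gene mdcE (bll0267) rose by 0.48 ± 0.19, with a wide spread between materials. The nodulation gene nolZ (bsl2015) rose by 0.44 ± 0.012, and the ferredoxin genes fer3 (bsr1750) and fer2 (blr1765) by 0.43 ± 0.15 and 0.38 ± 0.019. The call on fer3 was lost on the 3 arrays with bacteroid cDNA in Cy3 (adjusted p = 0.055). The remaining genes of the highest 10 were nifQ, nifW and hupH, given with their groups.

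The lowest value among genes with a symbol belonged to fixK (bll2757), the copy known as fixK2, a regulator of genes for respiration at low oxygen. It was -0.65 ± 0.10 (adjusted p = 6.8e-04), a size of 4.50-fold if the base is 10 and 1.57-fold if it is 2. The manganese transporter gene mntH (bll5044) stood at -0.49 ± 0.085 and lpxC (bll6595), whose product acts early in lipid A synthesis, at -0.43 ± 0.068. cooxM (bll5664) stood at -0.42 ± 0.016. bkdA1 (blr6331), of branched-chain keto acid breakdown, stood at -0.40 ± 0.064, and the nucleoside diphosphate kinase gene ndk (blr4119) at -0.35 ± 0.11. The others of the lowest 10 were rhcJ, groEL, nolU and nolB, given with their groups.

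**Figure D1:**
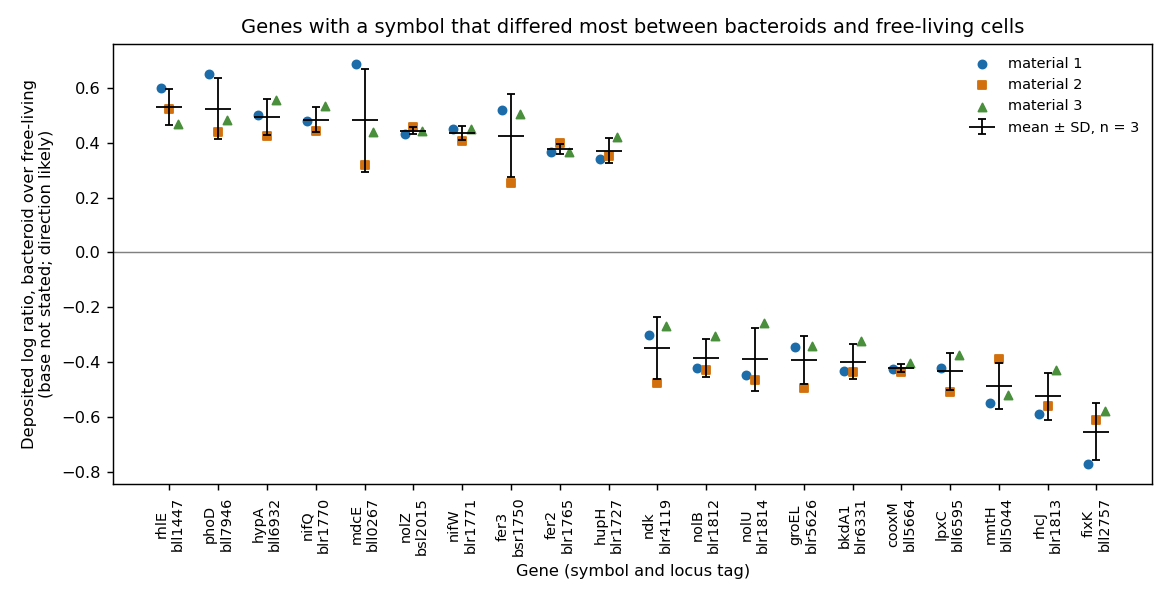
Deposited log ratio (vertical axis, base not stated, bacteroid over free-living likely) of the 10 highest and 10 lowest genes with a symbol; points are the 3 materials, bars the mean ± SD. The highest 10 had means between 0.37 (hupH blr1727) and 0.53 (rhlE bll1447), and the lowest 10 between -0.65 (fixK bll2757) and -0.35 (ndk blr4119).

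Genes with a nif symbol, most of them for nitrogenase and its assembly, were higher in bacteroids. Of 15 measured members, 11 rose and 0 fell, or 12 and 0 adjusted over the list alone, with a median of 0.28. nifQ (blr1770) rose by 0.48 ± 0.046 and nifW (blr1771) by 0.44 ± 0.026. nifH (blr1769), for the nitrogenase reductase, rose by 0.27 ± 0.063 (adjusted p = 0.0028), and nifK (blr1744), for a subunit of the molybdenum-iron protein, by 0.30 ± 0.13 (adjusted p = 0.0095). nifD (blr1743), for the other subunit, was at 0.06 ± 0.19 and did not pass (adjusted p = 0.53), nor did the activator gene nifA (blr2037) at 0.17 ± 0.17 (adjusted p = 0.090). Both had a value below 0 in material 2 alone, and without that material nifD was at 0.17 (adjusted p = 0.0033) and nifA at 0.27 (adjusted p = 9.9e-04). The list was shifted up by camera (adjusted p = 1.1e-08), a call lost with an estimated correlation (adjusted p = 0.75 with an estimated correlation).

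The fix genes went both ways. Of 23 members, 4 rose (fixB, fixC, fixX and fixU) and 6 fell (fixK bll2757, fixN, fixJ, fixL, fixR bll2623 and fixK bll6061), the same counts as adjusted over the list alone. The list's median was -0.06 and its test did not pass (camera adjusted p = 0.47); without members from the symbiotic stretch of locus numbers the list was called lower with the preset correlation (adjusted p = 0.044), a call lost with an estimated one (adjusted p = 0.81 with an estimated correlation). fixC (blr1774) rose by 0.28 ± 0.052 and fixX (bsr1775) by 0.31 ± 0.10, whereas fixA (blr2038) stood at -0.0013 ± 0.017. fixN (blr2763), for a subunit of the high-affinity terminal oxidase, was at -0.29 ± 0.043 (adjusted p = 0.0015), and the response regulator gene fixJ (bll2759) at -0.10 ± 0.0093 (adjusted p = 0.017). The genes numbered after fixN did not pass. They were fixO at -0.16 ± 0.17, fixQ at -0.15 ± 0.24, fixP at -0.07 ± 0.12 and fixG (blr2767) at -0.06 ± 0.12. Next came fixH at -0.06 ± 0.037, fixI at 0.02 ± 0.020 and fixS at 0.05 ± 0.073. The other fixK copies had small values: -0.10 ± 0.053 for bll6061 (adjusted p = 0.039), -0.05 ± 0.032 for bll2109, -0.07 ± 0.11 for bll3466 and 0.03 ± 0.056 for bll7696. Of the fix genes 2 were lower without material 1 or material 3, against 6. The call on bll6061 was lost when any of the materials was left out and with each array centred (adjusted p = 0.051), and that on fixJ without material 1 (adjusted p = 0.11) or material 3 (adjusted p = 0.081).

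Genes of the uptake hydrogenase, which oxidises the hydrogen that nitrogenase releases, were shifted up. Of 35 members, 12 rose and 4 fell (14 and 4 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.0030; adjusted p = 0.43 with an estimated correlation). In the copy at locus numbers near the nif genes, hupS (blr1720) rose by 0.22 ± 0.035, hupL (blr1721) by 0.23 ± 0.020 and hupH (blr1727) by 0.37 ± 0.044. Of the 12 members in the symbiotic stretch 5 rose, and of the 23 elsewhere 7 rose, hypA (bll6932), hupF (bsl6938, 0.29) and hupC (bll6940, 0.26) among the latter. The hupS and hupL copies elsewhere were at 0.0086 ± 0.051 for hupS (bll6942) and 0.12 ± 0.10 for hupL (bll6941), and neither passed (adjusted p = 0.84 and 0.066); hupL bll6941 passed without material 2 (0.18, adjusted p = 0.0062). The 4 lower members were hupV, hupU, hupA and hup; the names hupA and hup are also used for a DNA-binding protein. With members from the symbiotic stretch left out the median was the same 0.05 and p was 0.015 before adjustment and 0.053 after. The lower members numbered 2 without material 1 or material 3.

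Genes with a nodulation symbol (nod, nol or noe) were split. Of 31 members, 10 rose and 7 fell (13 and 7 adjusted over the list alone), and the list's test did not pass (median 0.04, camera adjusted p = 0.099). nodC (blr2027), for the enzyme that builds the backbone of the nodulation signal, rose by 0.17 ± 0.063 (adjusted p = 0.010), a call lost without material 1 (adjusted p = 0.055) or 3 (adjusted p = 0.057). nodA (blr2025) was at -0.25 ± 0.071, and the regulator gene nodD1 (bll2023) at 0.04 ± 0.032 (adjusted p = 0.21). Of the lower members, nolB (blr1812) at -0.38 ± 0.069, nolU (blr1814) at -0.39 ± 0.12 and nolV (blr1815) at -0.31 ± 0.12 have locus numbers among those of the type III secretion genes. Their symbols placed them here and not in the type III list. Apart from nodA, the remaining lower members lie outside the symbiotic stretch: nodQ (bll1475, -0.18) and the nodN copies bll3460 (-0.08) and blr3959 (-0.14). The split is thus mostly not one within the nod cluster. The counts were 4 higher and 4 lower without material 1, and 3 and 5 without material 3.

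The type III secretion genes, for the apparatus that exports proteins toward the host cell, were lower in bacteroids. Of 10 members, 0 rose and 7 fell, also when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0017; adjusted p = 0.76 with an estimated correlation). rhcJ (blr1813) was at -0.52 ± 0.086 (adjusted p = 8.2e-04), rhcQ (blr1818) at -0.31 ± 0.11 and rhcR (blr1819) at -0.26 ± 0.083. rhcC1 (bll1811), rhcC2 (bll1842) and rhcT (blr1821) did not pass. Without material 1 the lower members numbered 3. With 10 genes of 1 cluster the members are not independent of each other.

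The symbiotic stretch is the run of locus numbers, starting at 1700, that holds the nif, hup, nod and type III secretion clusters. Of its 353 measured genes, 140 rose and 32 fell (155 and 33 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 1.4e-12; adjusted p = 0.21 with an estimated correlation). Its largest value belonged to bll1875, a gene without a symbol, at 0.85 ± 0.020 (adjusted p = 9.5e-05).

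**Figure D2:**
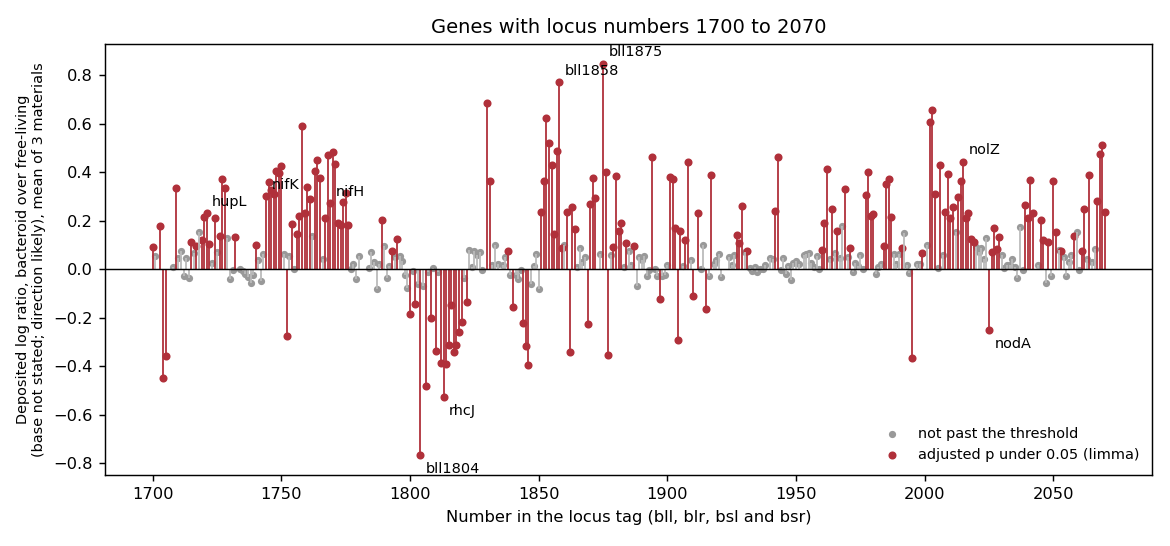
Mean deposited log ratio over 3 materials (vertical axis, base not stated, bacteroid over free-living likely) by the number in the locus tag (horizontal axis, from 1700 upward); red stems passed the threshold and grey stems did not. Of 353 genes 140 were higher and 32 lower, and 9 of the 10 genes with locus numbers 1810 to 1819, rhcJ (blr1813, -0.52) among them, were lower.

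Chaperone and heat shock genes were lower as a group. Of 31 members, 1 rose and 12 fell (2 and 13 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0017; adjusted p = 0.43 with an estimated correlation). The chaperonin copy groEL (blr5626) was at -0.39 ± 0.088 (adjusted p = 0.0018) and its neighbour groES (blr5625) at -0.31 ± 0.063. The groEL copy in the symbiotic stretch (bll2059) was at 0.15 ± 0.13 (adjusted p = 0.069). The 1 higher member was clpS (bll2636). The counts were 0 higher and 6 lower without material 1, 3 and 13 without material 2, and 0 and 7 without material 3.

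Amino acid biosynthesis genes were lower, with 5 of 98 members higher and 28 lower (6 and 28 adjusted over the list alone) and a median of -0.05 (camera adjusted p = 0.0056; adjusted p = 0.84 with an estimated correlation). The aspartate kinase gene lysC (blr0216) was at -0.31 ± 0.16 (adjusted p = 0.014), dapD (blr8104), of lysine synthesis, at -0.29, and the methionine synthase gene metE (blr5608) at -0.24. The pattern on symbols also took in aminoacyl-tRNA synthetase genes, of which serS (bll4748) at -0.19 and trpS (bll0802) at -0.14 were among the lower members. The counts were 1 higher and 9 lower without material 1 and 1 and 8 without material 3. Without material 2 the list was no longer called (median -0.03, adjusted p = 0.078).

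Haem and iron uptake genes had 0 of 19 members higher and 9 lower (1 and 10 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.018; adjusted p = 0.76 with an estimated correlation). The iron response regulator gene irr (bll0768) was at -0.25 ± 0.080 (adjusted p = 0.0050), hemN (bll7086) at -0.21 and hemA (bll1200), the entry to haem synthesis, at -0.13. With robust moderation this list was not called (adjusted p = 0.064). In that setting, and with the material as a random replicate block, the list test also ran on the t values of the genes. The main test ran on their values per material. A call lost in either setting thus cannot be put down to moderation or block alone. The Calvin cycle list had 0 of 9 members higher and 2 lower (0 and 5 adjusted over the list alone), the aldolase gene cbbA (blr2584) at -0.17 ± 0.045 and the large-subunit gene of Rubisco, cbbL (blr2585), at -0.17 ± 0.043. Its median was -0.08 (camera adjusted p = 0.046; adjusted p = 0.76 with an estimated correlation), and the call was also lost without material 1 (adjusted p = 0.092) or 3 (adjusted p = 0.091), with the material as a random replicate block (adjusted p = 0.14), with robust moderation (adjusted p = 0.14) and on the arrays with bacteroid cDNA in Cy3 (adjusted p = 0.059). Of the haem and iron uptake genes 3 were lower without material 1 and 2 without material 3, against 9; of the Calvin cycle genes 5 were lower without material 2.

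In all, 22 lists were tested and 8 were called, 3 higher and 5 lower. With an estimated correlation 0 were called, 1 having passed at an unadjusted p under 0.05 (the symbiotic stretch, p = 0.0098). The estimate lay below the preset 0.01 for the symbiotic stretch (0.0043), uptake hydrogenase (-0.0024) and chaperones (-0.026). Camera with an estimated correlation also relies on the 2 residual degrees of freedom. The calls lost in these lists therefore do not show that their genes moved together. In simulated data with independent genes, a list of 19 genes moved by 0.1 had a camera adjusted p of 2.6e-17 with the preset correlation and 0.58 with the estimated one.

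Ribosomal protein genes differed in sign between materials. Their median over 52 members was 0.11 in material 1, -0.24 in material 2 and 0.08 in material 3. Over all materials 3 rose (rplU, rpsO and rpmA) and 3 fell (rpmD, rpsT and rpsU), or 0 and 1 adjusted over the list alone. The camera test pointed up without passing (adjusted p = 0.88) while the median (-0.01) and mean (-0.01) lay below 0. Without material 1 or 3, 0 rose and 1 fell. Without material 2, 29 rose and 3 fell, and the list was called higher with the preset correlation (median 0.09, adjusted p = 2.4e-07). That call was lost with a correlation estimated on the same materials (adjusted p = 0.71 with an estimated correlation). rpmD (bsl5382) was at -0.26 ± 0.20 (adjusted p = 0.047), a call lost without material 1 (adjusted p = 0.055) or 3 (adjusted p = 0.099), and with each array centred (adjusted p = 0.052).

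Material 2 also stood below the others in genes of energy metabolism, and had the lowest median of the 3 materials in 19 of 23 lists. The ATP synthase list had medians of -0.0070, -0.18 and -0.02 in materials 1, 2 and 3, and 0 of 8 members passed over all materials or adjusted over the list alone (camera adjusted p = 0.30). For NADH dehydrogenase I the medians were 0.02, -0.10 and -0.0021; 0 of 13 rose and 2 fell in either adjustment, nuoB (bll4918) at -0.16 ± 0.063 and nuoC (bll4917) at -0.09 (camera adjusted p = 0.30). For the TCA cycle the medians were 0.03, -0.09 and -0.02; 1 of 14 rose (citA, 0.17) and 3 fell in either adjustment, with citrate synthase gltA (blr4839) at -0.24 ± 0.063 and mdh (bll0456) at -0.22 (camera adjusted p = 0.68). The call on nuoB was lost without material 1 (adjusted p = 0.063). Without material 1, 2 and 3, NADH dehydrogenase I had 0, 1 and 0 genes higher and 0, 2 and 1 lower, the TCA cycle 0, 2 and 0 higher and 2, 3 and 3 lower, and ATP synthase 0, 1 and 0 higher. The nif list kept its sign, with medians of 0.32, 0.21 and 0.31.

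Denitrification genes showed little shift, with 2 of 18 higher and 1 lower (1 and 0 adjusted over the list alone), a median of 0.00021 and a camera adjusted p of 0.30. nosZ (blr0315), for nitrous oxide reductase, rose by 0.13 ± 0.037 (adjusted p = 0.012), a call lost without material 1 (adjusted p = 0.085) or 3 (adjusted p = 0.080), and nirK (blr7089), for nitrite reductase, was at 0.05 ± 0.17 (adjusted p = 0.60). Flagella and chemotaxis genes had 2 of 61 higher and 9 lower (1 and 9 adjusted over the list alone) with a median of -0.02 (camera adjusted p = 0.30). fliE (bll5812), of the basal body, was at -0.24 ± 0.042, and the flagellin gene fliC (bll6855) at -0.09 ± 0.019 (adjusted p = 0.027), a call lost without material 1 (adjusted p = 0.16) or 3 (adjusted p = 0.13). Denitrification genes had 0 higher and 0 lower without material 1, 1 and 1 without material 2, and 1 and 0 without material 3. Without material 1, 0 flagella and chemotaxis genes were higher and 2 lower; without material 3, 0 of these were higher and 4 lower. None of the 7 copies of dctA, a dicarboxylate transporter gene, passed; the highest was bll1718 at 0.16 ± 0.12 (adjusted p = 0.054), which passed without material 2 (0.19, adjusted p = 0.024), and the lowest blr4298 at -0.08 ± 0.040 (adjusted p = 0.054). The sigma factor genes rpoN1 (blr1883) at 0.01 ± 0.028 and rpoN2 (blr0723) at 0.08 ± 0.071 did not pass.

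**Figure D3:**
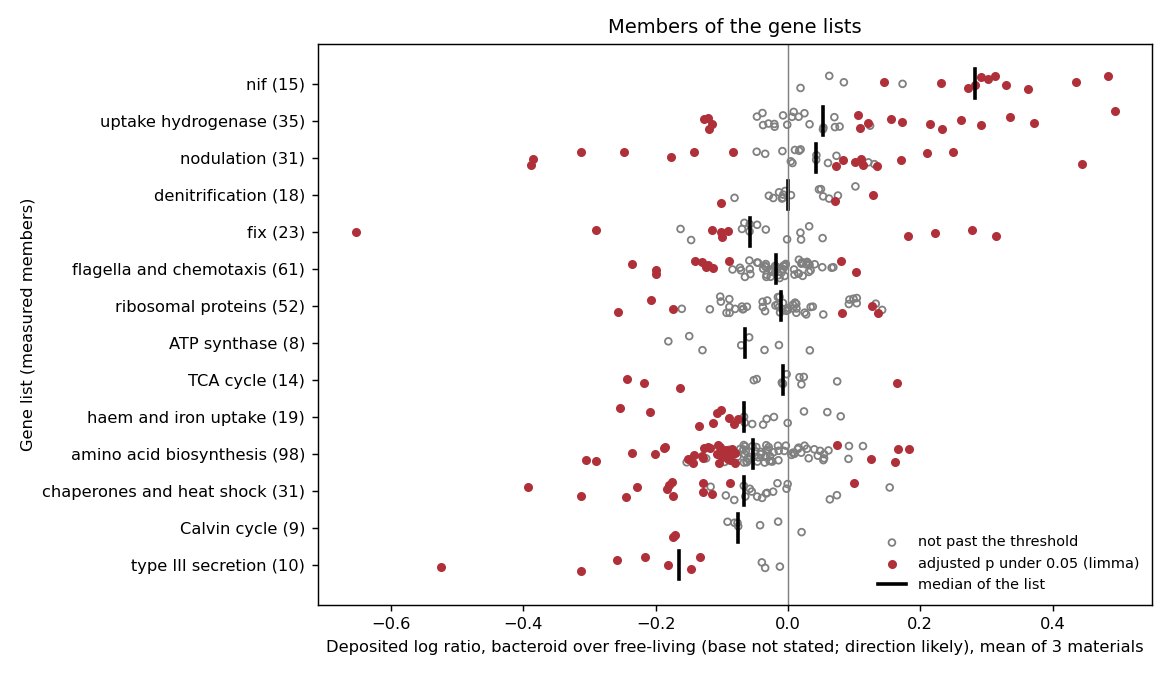
Mean deposited log ratio over 3 materials (horizontal axis, base not stated, bacteroid over free-living likely) of the members of 14 gene lists; filled points passed the threshold, open points did not, and black bars are list medians. The nif list has its median at 0.28 and 0 members called lower, and the type III secretion list its median at -0.16 and 0 called higher.

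The agreement of the arrays was compared next. Across rows, which are not independent replicates, the swapped arrays of 1 material correlated with r between 0.890 and 0.937, and the 12 pairs of arrays from different materials with r between 0.662 and 0.874 (median 0.755). All pairs were positive, dye swaps included, so the arrays had been turned the same way before deposit. The mean values of materials 1 and 3 correlated with r = 0.885, and those of material 2 with r = 0.758 against material 1 and 0.740 against material 3. Where a gene had a row whose name carried a suffix beside a plain row (191 pairs), the rows correlated with r = 0.348, so averaged values of such genes can hide a disagreement.

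Whether a ratio followed the dye was tested from the difference within each swapped pair. By limma 0 of 8091 genes passed, and 0 by a plain one-sample test, with 72 genes at an unadjusted p under 0.05 where chance gives 404.55. The dye differences of the 3 materials also correlated negatively (r between -0.211 and -0.151), so they did not vary independently as the test assumes. The 0 calls therefore cannot show that no ratio followed the dye. The cause was not tested.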

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

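The base 10 size limits, the shorter uptake hydrogenase list and the estimated correlation for the ribosomal protein list without material 2 and the fix list without the symbiotic stretch were chosen after seeing the data; the other alternatives were planned. The count of 2293 changed genes ranged from 924 to 2497 with a material left out: 924 without material 1 (919 of them among the 2293), 1150 without material 3 (1121 among them) and 2497 without material 2 (2025 among them), with no sign reversed among the kept genes. It was 5233 over 6 arrays with the material as a fixed replicate block, whose residual is the spread between swapped arrays of the same RNA, and 3728 with 6 arrays as independent. A plain one-sample test gave 1, a gene not among the 2293; it has 2 residual degrees of freedom. Limma's treat against 1.2-fold gave 686 for base 10 and 68 for base 2. A size of at least 1.5-fold left 819 and 29, and of 2-fold 260 and 0. The random replicate block gave 2606 (2167 shared), centring 2214 with 50.1% higher against 44.2%, scaling 2450, bacteroid cDNA in Cy3 alone 1780 and in Cy5 alone 2062; other settings for missing values, rows and robust moderation gave 2281 to 2318. Of the 8 called lists 0 were called with an estimated correlation and 4 with fry (nif, uptake hydrogenase, chaperones, symbiotic stretch). Without members from the symbiotic stretch 4 of 19 were called, 3 of them among the 8 and the fix list added. The nif and type III secretion lists, with 12 of 15 and 10 of 10 members in the stretch, were then too short to test. The stretch list itself was left out. The uptake hydrogenase and Calvin cycle lists were tested and lost their call (camera adjusted p = 0.053 for each). Other settings gave 6 to 8. The median correlation between arrays of different materials was 0.755 by Pearson and 0.657 by Spearman. The dye effect gave 0 genes in every setting run. Over named genes, 448 of 496 settings kept the direction and side of the threshold, 25 lost the call, 12 gained it and 11 turned the direction. Of the lost calls, 3 came with bacteroid cDNA in Cy3 alone and 3 in Cy5 alone, and not all of these genes are named with their results. For lists 231 of 264 kept both, 21 lost the call, 2 gained it and 10 turned the direction. None of the turned values was past the threshold on either side. The ranges below over materials left out also hold values that did not turn. Some of those passed, such as nifD at 0.17 and the ribosomal protein list at 0.085. Among genes they were fixA (0.0062 centred, 0.0019 scaled, 6.2e-05 in Cy3 alone), dctA bll7095 (0.0045 centred) and, over materials left out, fixA (-0.01 to 0.0065), dctA bll7095 (-0.0087 to 0.0027), hupS bll6942 (-0.018 to 0.033), nifD (-0.0012 to 0.17), rpoN1 (-0.0051 to 0.021) and nirK (-0.036 to 0.14). Among lists, by the direction of the test, they were ribosomal proteins (median -0.0028 centred, -0.011 in Cy3 alone, -0.010 with fry and with robust moderation, and -0.082 to 0.085 over materials left out), nodulation without the symbiotic stretch (-0.028), and, over materials left out, ATP synthase (-0.089 to -0.017), NADH dehydrogenase I (-0.063 to 0.0032) and TCA cycle (-0.042 to 0.013). The cause of these changes was not tested except where given. Treating repeated limit values as missing was not run, since 1 value in all columns was a repeat and it did not lie at a limit. Signal over background was not used here, so its limit on weak spots is unknown.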

Other observations

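Other gene groups also held members that moved. Since 27.9% of all genes passed, called members in a group are not a result about that group by themselves. Among cell division and wall genes 0 of 19 rose and 7 fell (0 and 7 adjusted over the list alone), with the septum-placement gene minC (blr4211) at -0.21 ± 0.033 and ftsZ (bll6596), for the division ring, at -0.10, although the list's test did not pass (camera adjusted p = 0.12). The call on minC was lost with the 6 arrays in a random replicate block (adjusted p = 0.066) and on the arrays with bacteroid cDNA in Cy3 (adjusted p = 0.067). DNA replication and repair genes went both ways, 5 of 27 higher and 6 lower in either adjustment (camera adjusted p = 0.68). recA (bll5755) rose by 0.23 and the gyrase gene gyrA (bll4696) by 0.17, while the replication initiator gene dnaA (bll0830) was at -0.18. The lowest member, ligE (bll7427) at -0.26 ± 0.042, entered the list through its symbol alone. Its product is not given, so it may not be a DNA ligase gene. Among oxidase and cytochrome genes 3 of 33 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.43), from cyc4 (bll5053) at 0.28 ± 0.13 to cycC (bll5913) at -0.21; the call on cyc4 was lost without material 3 (adjusted p = 0.055). Copies of phbB, of polyhydroxybutyrate synthesis, moved apart, blr3725 at 0.29 ± 0.073 and bll0225 at -0.23, and that list had 1 of 5 higher and 2 lower in either adjustment (camera adjusted p = 0.68). The sigma factor list took in any gene with an rpo symbol, which RNA polymerase core genes also carry, so not all members need be sigma factors. Of its 8 members 1 passed in either adjustment (list camera adjusted p = 0.30). This was the heat shock sigma factor gene rpoH2 (blr7337) at 0.29 ± 0.15, a call lost without material 3 (adjusted p = 0.062). These counts changed with a material left out. Cell division and wall genes had 1 lower without material 1 or 3 and 4 without material 2. DNA replication and repair genes had 3 higher and 1 lower without material 1, 5 and 7 without material 2, and 3 and 3 without material 3. Oxidase and cytochrome genes had 1 higher and 2 lower without material 1 or 3, and 3 and 4 without material 2. The polyhydroxybutyrate list had 1 higher and 1 lower without material 1 or 3, and 2 and 2 without material 2. The list of genes with an rpo symbol had 1, 4 and 0 higher without material 1, 2 and 3. The trehalose gene otsA (bll0322) rose by 0.13, 1 of 2 in its list in either adjustment, a call lost without material 1 or 2. Of 6 exopolysaccharide genes 0 passed in either (camera adjusted p = 0.43), and 1 was higher without material 2.

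Several of the largest values belonged to genes without a symbol, chosen here after their values were seen. On the higher side the first 4 were bll8223 at 0.92 ± 0.036, which is 8.30-fold if the base is 10 and 1.89-fold if it is 2, bll0735 at 0.89 ± 0.11, bll1875 at 0.85 ± 0.020 and bll0010 at 0.78 ± 0.013. On the lower side bll1804 came first at -0.77 ± 0.042, followed by fixK (bll2757) and then blr5658 at -0.64 ± 0.087. Called genes lay together: of 832 windows of 10 locus numbers, those from 1850 to 1859 and from 2010 to 2019 each held 9 higher genes of 10, where the highest count in any of 10000 shuffles of gene order was 8. The window from 1810 to 1819 held 9 lower genes of 10, a count reached in 4 of the 10000 shuffles. Outside the symbiotic stretch, the window from 1620 to 1629 held 8 higher genes. Windows outside it with 7 higher genes included those from 0 to 9, 2140 to 2149, 4340 to 4349 and 8210 to 8219. Dense windows of higher genes were thus not particular to the stretch.

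All tests in the next paragraphs were chosen after the result was seen, except those on rows with a suffix and on exchanged materials. The tests on ribosomal protein genes took the place of 2 tests on the dye difference, whose values are given at the end.

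Ribosomal protein genes were lower in material 2 (median -0.24, quartiles -0.30 and -0.11) and higher in materials 1 and 3 (0.11 and 0.08). Of 52 genes, 50 had their lowest value in material 2, against 39.2% of all genes. With centring and scaling of the arrays applied, the median in material 2 was still -0.21. This outcome was nearly fixed beforehand and is no separate test. The arrays of material 2 already had medians of -0.0080 and -0.0093, and SDs over all arrays were 0.114 to 0.147. A fault of 1 array is argued against, because the higher of the medians on the swapped arrays of material 2 was -0.23. A difference in growth state of the cells stays open: medians of ATP synthase, NADH dehydrogenase I and TCA cycle genes were all lower in material 2 than in either other material, with differences of -0.074 or lower, but 19 of 23 lists had their lowest median there and the nif list differed by -0.11, so this is not particular to growth or energy genes. Whether the bacteroids or the free-living cells of material 2 differed cannot be read from ratios, and a bias at bright spots stays open, since intensities were not used here.

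The nif genes rose while fixK (bll2757) and fixN fell in the same materials. The fix genes numbered after fixN, from fixO (blr2764, -0.16) to fixS (bsr2770, 0.05), did not pass. Cross-hybridisation with other fixK copies is argued against, because the median of the other 4 copies was -0.056 (range -0.10 to 0.03) against -0.65. A single deciding material is argued against, because the smallest size in any material was 0.737 times the mean size. A lower output of all genes under FixK control was looked for in the nap, nir, nor and nos genes. Their median was 0.00021 against -0.0068 for all genes, with 2 called higher and 1 lower. This met the condition set against that explanation, a median not below that of all genes and called members mostly higher. Their quartiles of -0.012 and 0.060 lay on both sides of the median of all genes, however, so they decide nothing. The oxygen supply and growth phase of the free-living cells are not given in the sources used here and stay open, as does the unstated direction of the ratios.

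In 191 genes a row with a suffix in its name stood beside a plain row, and their values correlated with r = 0.348 and rho = 0.198. Of 21 pairs in which both rows passed, 15 had the same sign. Noise in the suffix rows is argued against, because their lowest correlation between materials was 0.748, and a compressed range is argued against, because their SD was 0.808 times that of the plain rows. Both kinds of row thus gave repeatable values that differed from each other. What the suffix stands for is not given in the sources used here, so probes against another part or strand of the gene stay open, and no biological explanation was tested.

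Exchanging the cell types within 1 material gave 4 splits, the real one included. The real one called 2293 genes and the highest other 0, and 1 of 4 splits was as large as the real one; these are too few splits for a share under 0.05.

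Fewer genes than chance gives had a small p for the dye, 72 against 404.55 (a ratio of 0.178), the dye differences of the 3 materials correlated with r of -0.151, -0.164 and -0.211, and turning the sign of 1 material gave 304, 395 or 454 such genes.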
